A study of Mus musculus with 6 samples.

How the data were processed

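Mouse embryos labelled embryonic day 7.5 were profiled by RNA sequencing, with 3 wild-type libraries (WT) and 3 libraries of the Rnf111 S254D knock-in (KI), grouped by the genotype in the labels. Per the labels' protocols, RNA was captured on oligo(dT) beads and libraries were made with the SMARTER mRNA-seq kit. Zygosity, sex, litter, the tissues kept at dissection and whether a library holds a single embryo or a pool were not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be partly technical. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool and the gene annotation were not given in the sources used here, and neither was the use of strand, so reads of overlapping and antisense genes cannot be told apart.

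The deposited table holds 21899 rows with a gene symbol and 6 value columns, whose names match the column names given in the labels, and no per-sample column was left unused. The labels refer to the table as raw counts, but its values are not whole numbers, and the deposited values are RPKM as judged from the values themselves. Multiplied by the merged exon length of each gene in GENCODE M21, the values of each library became whole multiples of a single step. Between 97.9% and 98.0% of the nonzero values under 2000 reads were whole within 0.05. The reference annotation, on the earlier build GRCm38, matched 21229 of 21877 symbols (97.0%) and served only for lengths, GC content, biotype, chromosome names and shared sequence, so no coordinates are given. Whether a read means a single read or a read pair is open. For 20 symbols listed more than once the row with the highest mean was kept, which dropped 22 rows.

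The step size gave the depth of each library, from about 9763000 reads in KI 2 to 13559000 in WT 3. For a low gene such as Rnf111, with 153 to 284 reads, counting error is smaller than the spread between replicates, while for Ripply2, with 25 to 71 reads, it is a sizeable part of it. Whole reads came out in all 6 libraries for 16705 of 17073 genes with reads and a length (97.8%).

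A count-based quasi-likelihood test had been planned for the case of raw counts. Because the unit was RPKM, the planned replacement was used, limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) with a mean-variance trend and a robust prior. Log2 differences are on the log2(RPKM + 1) scale, which understates the change of low genes. Genes with at least 1 RPKM in at least 3 libraries were tested (10104), KI against WT, with no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Rnf111 also had an exact two-sided permutation test over 20 arrangements. The 26 gene lists, with their members, were written from textbook knowledge before the data were examined, as were the comparison, the rule for named genes and most of the alternative settings. They covered Nodal targets and pathway components, BMP and Wnt targets, germ layers and extraembryonic tissues, maternal decidua, blood, Hox genes, cell state, the SUMO pathway, Y-linked genes, ribosomal protein genes and mitochondrially encoded transcripts. Lists with at least 5 tested members (25) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. No list was called with an estimated correlation (lowest adjusted p = 0.83), and none by fry, in either its directional or its mixed form. Camera compares a list with all other genes, while fry asks whether the list moves at all.

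Named genes were Rnf111, then up to 12 per direction among genes past the threshold with separated groups. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were named as not past it. Gene models without a regular symbol and pseudogenes were counted but not named. From each list up to 4 members were named, those that passed and then those with the highest mean RPKM. Some genes that this rule selects are not reported here. Other genes named in the text were chosen after their values were seen.

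Libraries were compared pairwise over genes with at least 50 reads in the pair. The mean chi-square per gene was 3.70 for WT 1 and WT 2, 9.56 to 14.0 among the other pairs of WT 1, WT 2, KI 1 and KI 3, and 31.7 to 144 for pairs with WT 3 or KI 2. Values of 1 would mean sampling noise alone, so no pair was merged. The test was checked on simulated data with 200 genes changed by known folds. With the spread of all 6 libraries, over 9571 genes, it found 1 of 55 genes changed 1.5-fold, 9 of 73 changed 2-fold and 54 of 67 changed 4-fold, with 5 false calls. With the spread of WT 1, WT 2, KI 1 and KI 3 alone, over 9616 genes, it found 25 of 54, 50 of 74 and 67 of 68, with 6 false calls. The simulated genes varied independently, and no simulated library stood apart as WT 3 and KI 2 did.

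Alternatives covered the scaling, the pseudocount (0.1), the expression filter, limma-voom on the recovered reads, the replicate number as a block, each library left out, and a covariate of Y-linked expression. Among KI libraries only KI 2 reached the Y-linked level of WT, so the fit with that covariate sets mostly KI 2 against WT. Chosen after seeing the data were library weights, a GC correction (GC known for 9928 genes, 98.3%), a prior without trend, quantile normalization, WT 1 and WT 2 averaged, and both WT 3 and KI 2 left out. The share of 50-base subsequences that a gene's longest transcript shares with other genes' transcripts was counted in GENCODE M21 for list members. Data were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Xist was not analysed here.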

Results

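Gene expression was measured by RNA sequencing in mouse embryos labelled embryonic day 7.5, in 3 wild-type (WT) libraries and 3 libraries from embryos carrying the Rnf111 S254D knock-in (KI). Rnf111, also called Arkadia, is a RING-type ubiquitin ligase known to promote Nodal and TGF-beta signalling by driving the degradation of the Smad repressors Ski and Skil, and to recognise SUMO-modified proteins. The comparison addresses how the mutant allele affects transcript levels in the embryo. The table listed RPKM, reads per kilobase of exon scaled to the depth of the library, for 21877 gene symbols. The library depths implied by these values were about 13321000, 12677000 and 13559000 reads in WT replicates 1, 2 and 3. In KI replicates 1, 2 and 3 they were about 11507000, 9763000 and 11527000 reads. At the depth of KI 2, 1 read over 2 kb of exon was worth 0.0512 RPKM. The number of genes at 1 RPKM or more was 8912 in WT 3 and between 9738 and 10148 in the other 5 libraries.

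The main differences between libraries did not follow genotype. WT 3 lay apart from all others on the first principal component, which held 61.5% of the variance, and KI 2 lay apart on the second, with 25.1%. The third, with 6.75%, placed the 3 WT libraries (2.13 to 10.3) above the 3 KI libraries (-14.9 to -3.01). Across genes, WT 3 correlated with the other 5 libraries at Pearson's r between 0.940 and 0.952 (log2 scale), while WT 1, WT 2, KI 1 and KI 3 correlated with one another at 0.988 to 0.996. WT 1 and WT 2 were the closest pair, and their reads still differed beyond sampling noise, with a mean chi-square of 3.70 per gene, so both were kept. That value does not settle whether they come from separate embryos.

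**Figure D1:**
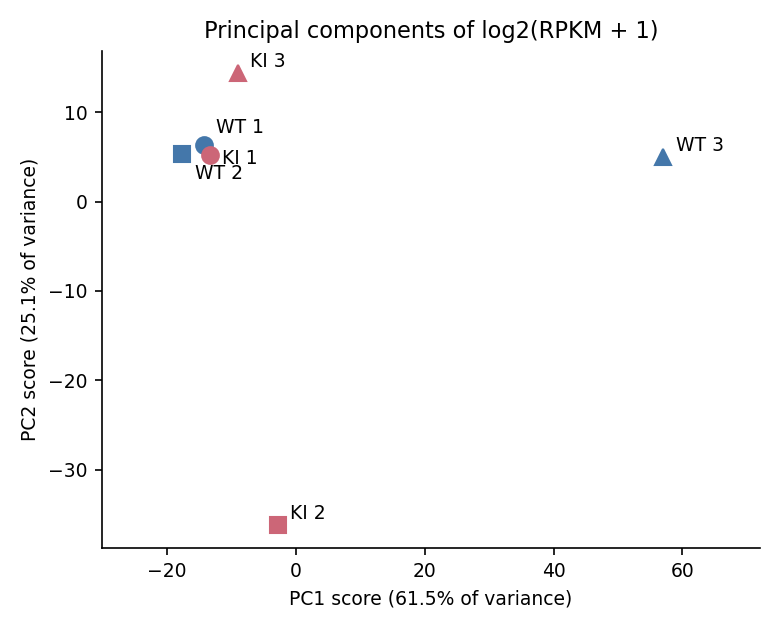
Scores of the 6 libraries on the first and second principal components of log2(RPKM + 1) over 10104 genes, with each axis giving its percent of the variance. WT libraries are blue, KI libraries are red and marker shapes give the replicate. WT 3 sits at 57.0 on the first component and KI 2 at -36.2 on the second.

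Rnf111 itself was expressed at a low level in both genotypes, with no detected difference between them. Its RPKM was 1.74, 2.53 and 2.12 in WT 1, 2 and 3 and 1.98, 2.57 and 1.5 in KI 1, 2 and 3, from 153 to 284 reads per library. The means were 2.13 ± 0.40 (SD, n = 3) and 2.02 ± 0.54 (SD, n = 3). The KI minus WT difference of -0.06 on the log2(RPKM + 1) scale was smaller than the spread between replicates (95% interval -0.53 to 0.41; exact two-sided permutation p = 0.8, where 3 against 3 cannot go below 0.1). The knock-in changes the protein sequence, so this level does not check the genotype labels.

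No gene changed between KI and WT past the threshold. The genes nearest to it included Ccn1, a secreted matrix-associated protein, whose 3 KI values of 62.9 to 89.7 RPKM all lay above the WT values of 38.7 to 40.1. Ripply2, a co-repressor active in somite segmentation, stood at 6.72 ± 1.44 in KI and 3.07 ± 0.53 RPKM in WT (SD, n = 3 each). Myf5, the early myogenic determination factor, stood at 3.54 ± 1.37 in KI and 10.2 ± 3.60 in WT. By limma on log2(RPKM + 1) with Benjamini-Hochberg adjustment, 0 of 10104 tested genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 121 genes, 63 higher and 58 lower in KI, against 505 expected from evenly spread p-values. Other splits of the 6 libraries into 3 and 3 gave 25 to 639, so the shortfall does not show fewer changes than chance. The voom form of limma on the recovered reads also made 0 calls, with 90 genes at an unadjusted p under 0.05. The count of 121 became 79 without WT 1, 453 without WT 3 and 59 without KI 1, and all these settings kept 0 calls.

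The 10 genes with the smallest unadjusted p, 5 in each direction, are given as genes that did not pass. Ccn1 had a log2 difference of 0.93 (SE 0.17, unadjusted p = 0.00069) and a KI mean 1.95 times the WT mean. The log2 difference of Ripply2 was 0.92 (SE 0.21), from only 25 to 71 reads per library. Strap, which binds TGF-beta receptor complexes, was at 277 ± 4.52 RPKM in KI and 198 ± 12 in WT (SD, n = 3 each), a log2 difference of 0.48. The ADP-ribosylhydrolase gene Macrod1 was near the detection limit, at 1.40 ± 0.27 in KI and 0.579 ± 0.114 in WT. The serine/threonine kinase gene Pim1 was at 15.9 ± 0.52 in KI and 9.01 ± 2.88 in WT. Myf5 had the largest difference of the 10, -1.30 on the log2 scale (SE 0.30, 95% interval -2.0 to -0.59), and a KI mean 0.348 times the WT mean. Saa1, an acute-phase serum amyloid gene, was at 0.696 ± 0.307 in KI and 2.03 ± 0.55 in WT. The calcium-binding protein gene S100a13 was at 4.58 ± 0.39 in KI and 7.69 ± 1.11 in WT. Lum, which encodes the matrix proteoglycan lumican, was at 40.7 ± 10.4 in KI and 67.9 ± 9.95 in WT. The retrotransposon-derived Rtl8a, on the X chromosome, was at 0.876 ± 0.254 in KI and 2.02 ± 0.58 in WT. In all 10 genes the 3 KI values did not overlap the 3 WT values. Over all tested genes 661 (6.54%) were separated in this way, 384 higher and 277 lower in KI, where chance gives 10%.

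**Figure D2:**
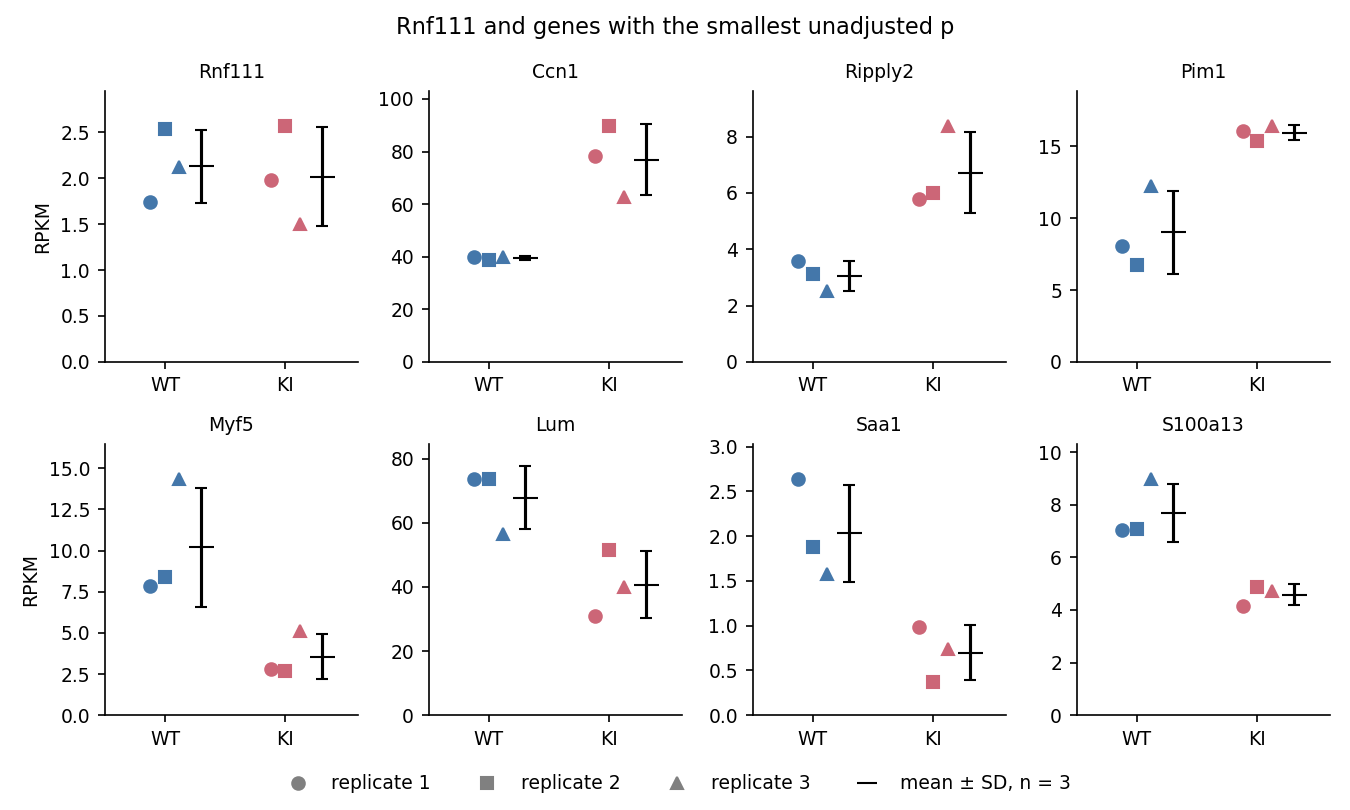
RPKM of Rnf111 and of 7 of the 10 genes with the smallest unadjusted p, per library (blue WT, red KI, marker shape by replicate), with the mean and SD of each genotype (n = 3). Rnf111 overlaps between genotypes, while all 3 KI values of Ccn1, Ripply2 and Pim1 lie above, and all 3 of Myf5, Lum, Saa1 and S100a13 below, the WT values.

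The error of these estimates was wide. The median SE of a log2 difference was 0.221 and the median 95% interval reached 0.517 to each side. In simulated data with the spread of all 6 libraries, the same test found 9 of 73 genes changed 2-fold and 54 of 67 genes changed 4-fold, over 9571 genes. No simulated library stood apart as WT 3 and KI 2 did, so these shares are only a rough guide to the real comparison. A pair of alternatives chosen after seeing the data did make calls. Weighting each library by its spread called 93 genes, 35 higher and 58 lower in KI, and leaving out WT 3 and KI 2 called 41, 18 higher and 23 lower. The 24 genes shared by both included Ccn1, Pim1, Strap and the caudal-type factor Cdx4 as higher, and Lum, Postn, Col1a1, the embryonic alpha-like globin gene Hba-x and Hoxd10 as lower. Of these, Postn, Col1a1 and Hoxd10 were picked after their values were seen. In the fit to all 6 libraries these genes did not pass. The Y-linked Kdm5d was also among the 24 as lower (log2 difference -1.15 with weights, -1.32 with both left out). Without WT 3 and KI 2 the summed log2 levels of Y-linked genes were 12.78 and 12.95 in WT against 5.5 and 0 in KI, so any call made without both cannot be separated from sex. The calls with weights rest mostly on KI 1 (weight 7.75) and WT 2 (3.41), against 0.110 to 1.25 for the other 4 libraries, and so come close to a comparison of 1 library per genotype that also differs in Y-linked expression.

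Transcripts of the visceral endoderm and yolk sac endoderm were low in KI 2, several of them nearly missing, and present at WT levels in KI 1 and KI 3. Apoa1, a yolk sac apolipoprotein gene, was at 0.414 RPKM in KI 2, 216 and 264 in KI 1 and KI 3, and 159, 159 and 458 in WT 1, 2 and 3. Rbp4, which encodes a retinol carrier, was at 4.96 in KI 2 and at 175 to 469 in the other 5 libraries. Ttr, the thyroid hormone carrier transthyretin, was at 2.76 in KI 2 and 52.5 to 248 elsewhere, and Apoe at 18.0 against 77.6 to 116. Of 17 tested members of this list, 15 had a negative and 2 a positive difference, and 0 passed singly. Over all 10104 tested genes, 5940 differences were positive and 4164 negative. The sign counts of this list and of those below are to be read against that background. The list fell in KI by camera with a preset correlation (mean log2 difference -0.96, adjusted p = 2.2e-05), and this call was lost with adjusted p = 0.83 with an estimated correlation. Without KI 2 the list was no longer shifted (adjusted p = 0.56) and its direction turned, and without WT 3 its adjusted p was 0.418; over 22 alternatives it ran from 2.2e-16 to 0.897. Without both WT 3 and KI 2 the list was called in the opposite direction, with KI higher (adjusted p = 5.4e-09).

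Heart genes were also low in KI 2. Myl7, the atrial myosin light chain, was at 58.7 RPKM in KI 2 and 156 to 201 in the other 5, cardiac actin Actc1 at 39.4 against 113 to 202, and troponin Tnnt2 at 1.74 against 11.2 to 13.7. Isl1, a regulator of heart progenitors, was at 12.4 ± 2.40 in KI and 16.3 ± 3.10 in WT (SD, n = 3 each). All 13 tested members of the cardiac mesoderm list had a negative difference, 0 passed singly, and the list fell (camera, mean log2 difference -0.45, adjusted p = 6.6e-06; adjusted p = 0.83 with an estimated correlation). Without KI 2 the adjusted p was 0.393, without both WT 3 and KI 2 0.123 and with library weights 0.112 (4.1e-14 to 0.897 over 22 alternatives). Unlike the yolk sac call, the cardiac call held without WT 3 (adjusted p = 0.00429). The extraembryonic mesoderm and allantois list fell as well, with 10 of 12 members negative (camera adjusted p = 0.0201; adjusted p = 0.83 with an estimated correlation). Its members Pmp22 and Bmp4 were at 33.1 and 8.02 RPKM in KI 2, against 94.1 to 101 and 18.7 to 22.7 elsewhere, while Msx1 (15.7 ± 5.93 in KI, 13 ± 7.39 in WT) and Msx2 (12.7 ± 4.03 and 14.2 ± 3.98) overlapped. That call ended without WT 1 (adjusted p = 0.0817), WT 2 (0.0775), WT 3 (0.0838) or KI 2 (0.938), without both WT 3 and KI 2 (0.599), with library weights (0.627) and with WT 1 and WT 2 averaged (0.0621), with 5.6e-05 as the lowest over 22 alternatives. The maternal decidua list fell with 7 of 8 tested members negative (mean log2 difference -0.35, camera adjusted p = 0.00707; adjusted p = 0.83 with an estimated correlation). Its granzyme genes Gzmd, Gzme, Gzmf and Gzmg were listed at 0 in every library, and tested members such as Lum, the smooth muscle actin gene Acta2 (177 ± 97.5 in KI, 206 ± 53.2 in WT), Des and the posterior Hox genes Hoxa10 and Hoxd10, are also expressed in embryonic mesoderm. Alpl (3.60 ± 0.12 in KI, 2.97 ± 1.0 in WT) went the other way. The decidua call ended without WT 1 (adjusted p = 0.141) or WT 2 (0.258) and with both averaged (0.0938), within 3.4e-06 to 0.897 over 22 alternatives.

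Among lists that rose in KI, the epiblast and pluripotency list had 7 of 8 tested members positive (mean log2 difference 0.37, camera adjusted p = 0.0127; adjusted p = 0.83 with an estimated correlation). The RNA-binding protein gene Lin28a was at 67.0 ± 3.23 RPKM in KI and 49.5 ± 11.4 in WT, the head regulator Otx2 at 8.13 ± 2.41 and 5.01 ± 1.37, and the DNA methyltransferase gene Dnmt3b at 10.8 ± 2.25 and 9.08 ± 0.98 (SD, n = 3 each). Sox2 was at 15.6 in KI 2 and 5.07 to 8.68 in the other 5 libraries, and 0 members passed singly. Otx2 and Sox2 are also active in neural tissue, and Pou5f1, Nanog, Utf1 and Fgf5 did not reach the expression minimum. The call ended without WT 1 (adjusted p = 0.141), with a Y-linked covariate (0.182), with no expression filter (0.339) and with WT 1 and WT 2 averaged (0.0611), within 0.0005 to 0.897 over 22 alternatives.

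The paraxial mesoderm and somite list rose, with 5 of 8 members positive (mean log2 difference 0.26, camera adjusted p = 0.0412; adjusted p = 0.83 with an estimated correlation). Adjusted over the list alone, Ripply2 passed (adjusted p = 0.0231 by limma), the only member of any list to do so, while over all genes tested it did not. The somite genes Meox1 (22.9 ± 6.95 in KI, 26.7 ± 10.9 in WT), Aldh1a2 (10.9 ± 4.11 and 10.7 ± 2.05) and Dll3 (5.31 ± 2.00 and 3.74 ± 2.55) differed by less than their spread. Leaving out a library ended the list call for WT 1 (adjusted p = 0.114), WT 2 (0.141), WT 3 (0.0927), KI 1 (0.0602) and KI 3 (0.0876), and with a Y-linked covariate it was 0.3; 5 of 22 alternatives kept it (0.0392 to 0.897).

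The immediate early and heat shock list rose, with 8 of 11 members positive (mean log2 difference 0.38, camera adjusted p = 0.0113; adjusted p = 0.83 with an estimated correlation). Junb was at 6.61, 10.02 and 4.52 RPKM in KI 1, 2 and 3 and at 4.53, 3.29 and 0.320 in WT 1, 2 and 3, and Egr1 and Atf3 were highest in KI 2, at 12.4 and 11.3. The chaperone genes Hspa8 (1706 ± 216 in KI, 1796 ± 306 in WT), Dnajb1 (47.6 ± 6.36 and 42.5 ± 10.6) and Hsph1 (30.9 ± 3.28 and 35.9 ± 7.83) and the immediate early gene Ier2 (98.4 ± 53.7 and 93.5 ± 8.38) showed no shift beyond their spread. Without KI 2 the adjusted p of this list was 0.393, and without WT 2 it was 0.0769. It was 0.124 with no expression filter, 0.543 without both WT 3 and KI 2 and 0.133 with library weights (1.3e-05 to 0.897 over 22 alternatives). The hypoxia and glycolysis list rose with 12 of 14 members positive (mean log2 difference 0.27, camera adjusted p = 0.0412; adjusted p = 0.83 with an estimated correlation). Lactate dehydrogenase Ldha was at 723 ± 128 in KI and 537 ± 197 in WT, Aldoa at 590 ± 61.3 and 453 ± 140, Eno1 at 648 ± 88.5 and 523 ± 270, and Pgk1 at 653 ± 122 and 602 ± 127 (SD, n = 3 each). Ldha, Aldoa and Eno1 were lowest in WT 3, which also had the lowest median log2(RPKM + 1) over all tested genes (2.49, against 2.79 to 2.97 elsewhere). The call ended without WT 2 (adjusted p = 0.0883), WT 3 (0.216), KI 1 (0.145) or KI 3 (0.771). It also ended with no filter (0.0531), with a pseudocount of 0.1 (0.074), with the replicate block (0.0554) and with WT 1 and WT 2 averaged (0.0611). The direction of the list turned with a Y-linked covariate (0.303), and its adjusted p ran from 3.4e-06 to 0.897 over 22 alternatives.

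**Figure D3:**
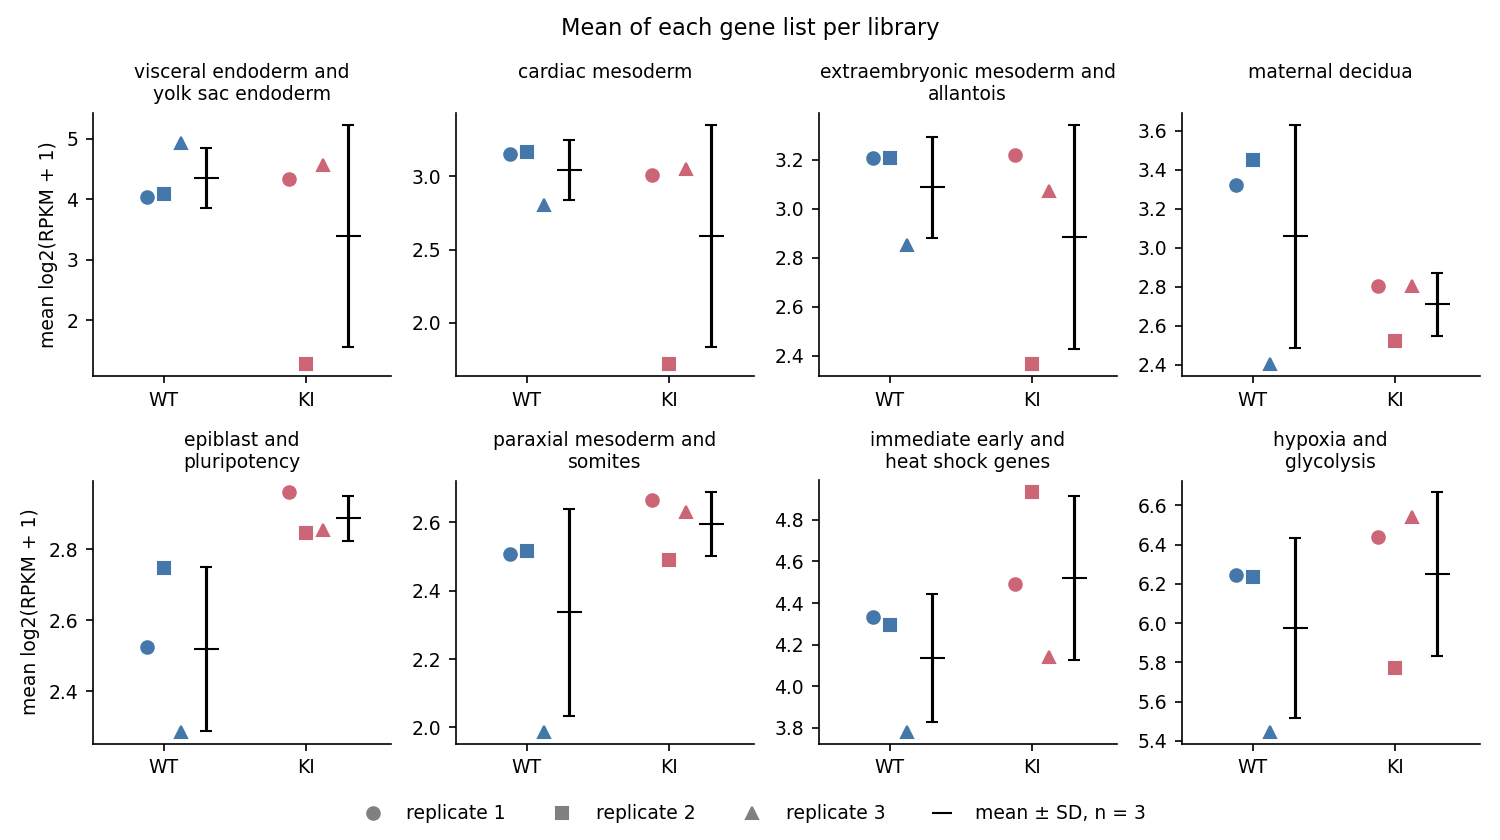
Mean log2(RPKM + 1) of the tested members of the 8 called lists in each library (blue WT, red KI, marker shape by replicate), with the mean and SD of the 3 libraries per genotype. Vertical axes do not start at 0. KI 2 lies lowest for yolk sac (1.28), cardiac (1.72) and extraembryonic mesoderm (2.37) genes, and WT 3 lies lowest for the other 5 lists. The median over all tested genes is also lowest in WT 3 (2.49, against 2.79 to 2.97 elsewhere), so its low list means are not particular to these lists.

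The testable readouts of Nodal and TGF-beta, the pathway in which Rnf111 is known to act, did not differ past the threshold in the fit to all 6 libraries. Among 10 tested target genes 6 had a positive and 4 a negative difference (camera adjusted p = 0.897, direction down, although the mean difference of 0.08 and the median of 0.01 were positive). Skil, a target of the pathway and a substrate of Rnf111, was at 19.5 ± 6.24 RPKM in KI and 25.1 ± 13.2 in WT, with 40.4 in WT 3. Mixl1 was at 6.41 ± 3.22 and 8.41 ± 7.43, and Fgf8 at 8.87 ± 0.87 and 6.07 ± 3.61 (SD, n = 3 each). Without both WT 3 and KI 2 the target list passed with KI higher (adjusted p = 0.016), as did its member Foxh1, a Smad-binding factor (log2 difference 0.96, limma adjusted p = 0.0286), which was at 10.5, 1.5 and 11.4 in KI 1, 2 and 3 and 4.67, 5.61 and 1.08 in WT 1, 2 and 3. Nodal itself did not exceed 0.188 RPKM in any library. The listed targets Lefty1, Lefty2, Gsc, Eomes and Pmepa1 were also too low to test, at no more than 0.414 RPKM. Any response of these genes could not be measured here. The pathway component list had 14 of 16 members positive (camera adjusted p = 0.144), where 5940 of all 10104 tested genes were positive. The receptor gene Tgfbr1 was at 15.6 ± 3.70 in KI and 13.6 ± 3.36 in WT, Trim33 at 16.9 ± 2.49 and 15.9 ± 6.98, and Tgif1 at 21.2 ± 2.85 and 21.1 ± 1.73. The pathway list passed without KI 3 (adjusted p = 0.0302) and with a Y-linked covariate (0.0172), with KI higher.

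The other signalling and germ layer lists gave no call in the fit to all libraries. BMP targets split 6 to 5 (camera adjusted p = 0.943), with Id3 at 126 ± 14.1 RPKM in KI and 106 ± 34.6 in WT, Id2 at 101 ± 30.5 and 82.6 ± 6.84, and Id1 at 31.2 ± 4.59 and 27.0 ± 11.4. Wnt targets had 8 of 11 members positive (adjusted p = 0.45), with Cdx4 at 78.9, 35.6 and 76.7 in KI 1, 2 and 3 and 41.2, 40.1 and 56.8 in WT 1, 2 and 3. Sp8 stood at 39.3 ± 4.43 in KI and 45.5 ± 33.5 in WT, Lef1 at 10.01 ± 0.62 and 8.29 ± 1.38, and Znrf3 at 25.6 ± 2.00 and 29.0 ± 5.76. The Wnt list passed without WT 3 (adjusted p = 0.0292) and without KI 2 (0.0252), without both (0.00016) and with library weights (0.00045), with KI higher. The primitive streak list, which holds the streak factor T (9.55 ± 2.61 in KI, 6.80 ± 0.50 in WT), Msgn1 (7.84 ± 2.34 and 7.36 ± 2.69) and Rspo3 (14.1 ± 2.51 and 11.7 ± 2.01), had 8 of 11 members positive (adjusted p = 0.112) and passed without KI 2 (0.0252). Definitive endoderm and axial mesendoderm genes split 5 to 5 (adjusted p = 0.983), with a median of -0.0017 and a mean of 0.11. Among them, Trh was at 20.6 and Krt18 at 119 in KI 2, against 0.959 to 6.72 and 329 to 436 elsewhere, and Dkk1 was at 4.65 ± 1.22 in KI and 4.2 ± 0.33 in WT. Neural and surface ectoderm genes were positive in 7 of 10 (adjusted p = 0.112). This list passed without WT 3 (0.0292) or KI 3 (0.03), with no expression filter (0.0442) and with a Y-linked covariate (0.0056). Pax3 was at 4.25 ± 0.70 and 3.37 ± 0.81, Dlx5 at 3.37 ± 1.11 and 3.66 ± 0.51, and Hesx1 was at 17.6 in WT 3 and 3.29 to 7.24 elsewhere.

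Blood and endothelial genes had 10 of 15 members positive (camera adjusted p = 0.897). The embryonic globin genes were highly expressed, with Hba-x at 853 ± 67.2 RPKM in KI and 1192 ± 224 in WT, Hbb-bh1 at 903 ± 47.8 and 766 ± 82.0, and Hbb-y at 408 ± 170 and 363 ± 200 (SD, n = 3 each). These genes belong to families of similar copies, so reads can be split between members. Etv2, a regulator of endothelial fate, was at 17.9 ± 10.2 and 13.4 ± 1.93. The list written for adult red and white blood cells (5 of 13 members tested, camera adjusted p = 0.217) did not shift past the threshold. It includes Hba-a1 at 231 ± 42.2 in KI and 232 ± 32.5 in WT, Hba-a2, Hbb-bs and Alas2. The levels of these genes are not taken as a measure of adult or maternal blood. Hox genes had 10 of 15 members positive (adjusted p = 0.881; 0.018 without both WT 3 and KI 2, with KI higher), with Hoxb1 at 17.8 ± 4.53 and 12.4 ± 6.04, Hoxa9 at 10.4 ± 4.65 and 9.98 ± 1.75, and Hoxb2 at 8.73 ± 3.43 and 6.94 ± 0.33. Trophoblast genes (8 tested, adjusted p = 0.406; 0.0382 with a Y-linked covariate, with KI lower) had a list mean of 2.19 in KI 2 and 3.12 to 3.37 in the other 5 libraries. Rhox5 was at 0.738 in KI 2 and 20.1 to 59.9 in the other 5, Phlda2 at 42.7 and 113 to 418, and Plac1 at 3.96 and 9.16 to 16.5, while Gjb5 was at 4.76 ± 1.33 in KI and 4.94 ± 0.91 in WT. Parietal endoderm genes (12 tested, adjusted p = 0.583) included Sparc at 16.3 ± 1.22 and 18.0 ± 5.07, Lamb1 at 7.67 ± 1.65 and 8.06 ± 1.79, Pdgfra at 5.66 ± 2.65 and 6.24 ± 2.45, and Col4a1 at 5.76 ± 0.95 and 5.21 ± 0.45.

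The remaining cell state lists did not pass in the fit to all 6 libraries. Proliferation genes (18 tested, camera adjusted p = 0.45) included Cdc20 at 278 ± 42.2 RPKM in KI and 260 ± 34.6 in WT, Ccnb1 at 205 ± 29.9 and 212 ± 11.2, Ccnb2 at 251 ± 3.66 and 228 ± 17.5, and Pcna at 176 ± 17.6 and 184 ± 26.8 (SD, n = 3 each). Targets of p53 (14 tested, adjusted p = 0.897) included Bax at 51.4 ± 2.82 and 45.3 ± 4.08, Mdm2 at 20.8 ± 1.33 and 18.0 ± 2.68, Ccng1 at 14.3 ± 2.84 and 15.1 ± 4.18, and Perp at 10.2 ± 1.67 and 12.2 ± 3.91. The SUMO pathway list (18 tested, adjusted p = 0.275), relevant to the SUMO-targeted activity of Rnf111, included Sumo2 at 441 ± 85.6 and 417 ± 21.2 and Sae1 at 235 ± 31.6 and 225 ± 52.4. Ribosomal protein genes (74 tested, 47 negative, adjusted p = 0.0873) included Rps6 at 1282 ± 155 and 1365 ± 210, Rpl41 at 1142 ± 170 and 1087 ± 60.4, Rpl4 at 1066 ± 14.2 and 1080 ± 90.2, and Rpl19 at 865 ± 40.4 and 912 ± 4.84. That list passed with KI lower under median-of-ratios (adjusted p = 0.0264) and upper-quartile scaling (0.0283), and without WT 1 (0.00386), WT 2 (0.0154) or KI 2 (3.4e-09). It also passed with KI lower by voom (0.037), with a GC correction (0.0176), with library weights (0.0169), without both WT 3 and KI 2 (0.00977) and with WT 1 and WT 2 averaged (0.00683). Its direction turned, without a call, under quantile normalization (0.933) and without WT 3 (0.0838), KI 1 (0.985) or KI 3 (0.994), and turned with a call with a Y-linked covariate (2.9e-04). The mitochondrially encoded transcripts (9 tested, adjusted p = 0.897) had camera direction down with a mean of 0.0073 and a median of 0.02. They passed with KI higher without WT 3 (0.0286) and with a Y-linked covariate (0.0101), and with KI lower without KI 2 (0.0395), and mt-Co1 was at 850 ± 276 in KI and 910 ± 292 in WT.

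The Y-linked genes showed that the genotypes were not balanced for sex. Ddx3y was at 17.1, 17.1 and 24.1 RPKM in WT 1, 2 and 3, at 24.7 in KI 2, at 3.24 in KI 1 and at 0 in KI 3. Eif2s3y, Uty and Kdm5d were also lowest at 0 in KI 3, next lowest in KI 1, and higher in the other 4 libraries. With 4 members this list was under the minimum of 5 for a test. Any sex difference in expression therefore falls partly along the genotype comparison of all 6 libraries, and wholly along it without WT 3 and KI 2. Among KI libraries only KI 2 reached the summed log2 Y-linked level of WT (13.48, against 12.78 to 14.52 in WT). The fit with the Y-linked covariate therefore sets mostly KI 2 against WT, and its results cannot be told apart from the divergence of KI 2.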

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

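The library weights, GC correction, prior without trend, quantile normalization, averaging of WT 1 and WT 2, and leaving out of both WT 3 and KI 2 were chosen after seeing the data. The count of changed genes stayed at 0 under 4 of these 6 settings and under all other settings run, among them an adjusted p under 0.1 and leaving out the yolk sac, trophoblast, decidua, adult blood and Y-linked list genes. Library weights gave 93 genes, 35 higher and 58 lower in KI, and leaving out WT 3 and KI 2 gave 41, 18 higher and 23 lower; the weights were 0.110 for WT 3, 0.395 for KI 2, 0.695 for WT 1, 1.25 for KI 3, 3.41 for WT 2 and 7.75 for KI 1, so that fit rests mostly on KI 1 and WT 2. Genes at an unadjusted p under 0.05 numbered 121, and 59 to 453 with a library left out, 372 with no filter, 565 with the Y-linked covariate, 1177 with both left out and 1600 with weights.

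The count of called lists, 8, was 5 with no filter, 5 with weights, 4 with WT 1 and WT 2 averaged, 0 with an estimated correlation, 0 by fry, 4 to 8 with a library left out, 9 under median-of-ratios and upper-quartile scaling and 10 with the Y-linked covariate. As signed -log10 p of camera (positive for KI higher), the yolk sac list turned to 0.446 without KI 2 (range -10.5 to 0.446 with a library left out), 0.950 with weights and 9.67 without both WT 3 and KI 2. The Nodal target list turned to 2.35 without both; these last 2 were calls with KI higher (adjusted p = 5.4e-09 and 0.016). As the same measure, the hypoxia list turned to -0.703 with the Y-linked covariate, the ribosomal list to 4.23 with that covariate, and the mitochondrial list to 2.34 without WT 3 (range -1.95 to 2.34) and 2.55 with the covariate. Results with the covariate rest mostly on KI 2 among the KI libraries and are not a clean adjustment for sex. As log2 differences, Hesx1 turned to 0.84 and Hbb-y to -0.62 without both libraries, and Rnf111 to 0.20 with the covariate, with a range of -0.19 to 0.068 with a library left out; it was above 0 without WT 2 or KI 3 and never passed. The cause was not tested, except that KI 2 alone holds the low yolk sac values.

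Of the 10 genes named by p, none changed sign. Since they were picked by p from these same libraries and their groups did not overlap, a kept sign was likely from the start and adds no support. Of their alternative values, 178 stayed on the same side of the threshold and 13 passed it, all in the 2 settings that made calls. The replicate block left 0 changed genes and 7 called lists, losing the hypoxia list (adjusted p = 0.0554). Deviations of same-numbered libraries correlated at 0.124, -0.051 and 0.0054, and no more than 1 WT library (WT 1, with KI 1) correlated best with its own number. These values show no pairing by number, but with the divergent WT 3 and KI 2 among the libraries they do not exclude one. Leaving out WT 3 moved the median of all genes by -0.10; median-of-ratios and upper-quartile scaling moved it by -0.06 and -0.07. A DESeq2 Wald test and TMM scaling were not run; limma-voom on the recovered reads was the only test of reads, and library-size scaling is the deposited one. Depth limits genes near 1 RPKM most.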

Other observations

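The tests of further yolk sac, heart and somite-stage genes were written before those genes were looked at, and the other tests of this part were chosen after the result was seen. Genes of later embryonic tissues were listed in all 6 libraries at low levels. Wnt1, a midbrain signal, was at 0.279 to 2.76 RPKM, Tfap2b, a neural crest factor, was at 1.58 to 2.75, and Pax8, an intermediate mesoderm and otic gene, was at 2.12 to 3.5. Fibrinogen genes of the yolk sac were at 5.61 to 16.1 RPKM for Fgb in the 5 libraries other than KI 2 and at 0.645 in KI 2. Troponin C, Tnnc1, was at 80.4 to 130 RPKM in the same 5 libraries and at 22.7 in KI 2.

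Yolk sac and heart transcripts were low in KI 2: of 14 further yolk sac endoderm genes, 12 were expressed and all 12 were lowest in KI 2, with a median log2 difference of -1.23 from the other 5 libraries. Of 10 further heart genes, 8 were expressed and all 8 were lowest in KI 2, with a median of -1.755. A loss in every KI library is argued against, since the yolk sac list means of KI 1 (4.33) and KI 3 (4.57) lay within the WT range of 4.04 to 4.92, and their average 0.098 above the WT mean; the cardiac list means of KI 1 (3.01) and KI 3 (3.05) also lay within the WT range of 2.81 to 3.17. The embryonic globin genes were not low in KI 2. Hba-x was at 918 RPKM there (784 to 1383 in the others) and Hbb-y at 603 (133 to 493). The tests here cover yolk sac endoderm genes, not the yolk sac as a whole. A KI 2 sample that lacked yolk sac endoderm and part of the heart may account for the low values of both sets. Whether such tissue was lost at dissection or failed to form, a variable effect of the genotype, was not tested and remains open. It is also open whether a library is a single embryo or a pool, and Ddx3y at 3.24 RPKM in KI 1, between 0 in KI 3 and 17.1 to 24.7 elsewhere, leaves a mixed KI 1 sample open too.

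WT 3 stood apart from the other 5 libraries. Its deviations from their mean fell with GC content (Spearman's rho -0.455 across 9928 genes, which are not independent replicates), with a mean of 0.134 in the 10% of genes with the lowest GC and -0.742 in the 10% with the highest. The GC trend held 19.7% of the variance of these deviations and a transcript length trend 6.57%, and after removing the GC trend their SD was still 0.549, against 0.212 to 0.275 in WT 1, WT 2, KI 1 and KI 3. Neither trend was the whole cause, and GC bias may be part of it. No biological explanation was tested, since the labels separate WT 3 from WT 1 and WT 2 by number alone.

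Part of the markers of the labelled stage were near 0. Of 35 epiblast and primitive streak genes in the table, 16 did not reach the expression minimum, among them Pou5f1 (0 in 5 libraries and 0.0386 RPKM in KI 3), Nodal, Eomes, Gsc, Mesp1 and Fgf5. Others were expressed, such as Lin28a (37.3 to 70.3), Rspo3 (9.59 to 15.7) and T (6.24 to 12.5), as were Myl7, the embryonic globin genes and Hoxa9. Loss of reads to exact copies in annotated transcripts is argued against for most of these 16 genes. They shared a median of 0.434% of their 50-base subsequences with other genes. While 7 shared none, the highest shares were 35.9% for Dppa4 and 15.9% for Pou5f1. Copies that differ slightly or lie outside the annotation were not counted, so loss of reads to those stays open. Embryos older than the label may account for the low stage markers. Of 12 genes of somite-stage embryos only 5 reached the minimum, between the bounds set beforehand for and against. An older stage therefore cannot be told apart from other differences in staging or dissection.

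With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 changed genes and the highest of the others 0. Every split gives at least 0, so that all 10 gave as many was fixed in advance and tells nothing. At an unadjusted p under 0.05 the real split gave 121 genes, the lowest other split 25 and the highest 639, with 7 of 10 splits as large. In called lists the real split gave 8 and the highest other 9, with 2 of 10 as large. The split with 9 lists set WT 1, WT 2 and KI 2 against the rest.

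Gapdh, used widely as a reference transcript, was listed at only 2.87 to 9.82 RPKM, and its longest transcript shared 27.8% of its 50-base subsequences with other genes. Actb was at 2793 to 6266 RPKM. Both genes were chosen after their values were seen, and the cause of the low Gapdh level was not tested.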
